A study of Mus musculus with 18 samples.

How the data were processed

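Small RNA of C2C12 cells was sequenced from 18 libraries: input RNA, eluates of the MRTF-A 3'UTR bait and eluates of an MS2 control, each from undifferentiated cells and from cells differentiated for 7 days, with 3 libraries per group. Per the labels, cells grew in medium with 10% fetal calf serum and were differentiated in 2% horse serum, and reads were 50 bp long. The labels give the same treatment text for undifferentiated samples, so the state was taken from the titles. Per the labels, baits with MS2 hairpins were held on amylose resin through a fusion of maltose-binding protein and MS2 coat protein.

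Per the submitters' processing notes, reads were processed with cutadapt 1.4.2, Bowtie2 2.0.13, featureCounts 1.4.6 and edgeR 3.18.1 on GRCm38/mm10. Settings, strand, the handling of reads that match several miRNAs and any filter are not given in the sources used here. The deposited signal of each miRNA and library is a normalised CPM by the authors. Within each library the values were whole multiples of a smallest step, so whole reads were recovered (100% within 0.01 read). The table totals and the step gave an effective library size for each library, and its normalisation factor matched a TMM factor recomputed over all 18 libraries within 4.88e-15. The log2 fold changes in the authors' deposited table are those of the first over the second group named in each file header, and base 2 was read from the values. The p-values and FDR values are by the authors, per the file headers. Only their counts of calls are given here. Their MS2 control against input comparisons, with 202 calls in undifferentiated and 165 in differentiated cells in the authors' deposited table, were not repeated.

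Of 2042 names, 438 had no read in any library. Depth per library was 314110 to 462847 recovered reads in differentiated and 294112 to 860828 in undifferentiated input, 306483 to 544504 and 107165 to 352674 in the MRTF-A eluates, and 15562 to 23433 and 20525 to 39695 in the MS2 control eluates. Factors were 0.341 to 0.609 in undifferentiated and 0.551 to 0.634 in differentiated MRTF-A eluates and 1.24 to 2.37 in the MS2 controls, so the scaling differs with the kind of library. All replicate pairs differed by more than sampling of reads (chi-square per degree of freedom of at least 5.38).

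The plan written before the data were examined named the edgeR quasi-likelihood test for counts and, for other units, limma with a trend. As the table holds a normalised signal, limma 3.58.1 in R 4.3.3 was the main test, on log2(CPM + 10), where 10 is the pseudocount. edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads were alternatives. miRNAs were kept by filterByExpr on the recovered reads with the deposited effective sizes, and p-values were adjusted by Benjamini-Hochberg within a comparison, with a threshold of 0.05. The 6 inputs were fitted for the input comparison, the 12 eluates for the bait, interaction and eluate comparisons, and all 18 libraries for bait against input. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the tables, sites and figures.

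miRNAs named in the text followed a rule written with the plan. It took the 12 largest rises and 12 largest falls in the input, 10 and 5 for each bait comparison and 5 and 5 elsewhere, among those with adjusted p under 0.05, a mean of at least 50 CPM in the higher group and no overlap of the groups. It added the myomiR and candidate lists, the 5 most abundant miRNAs of each group and 2 to 4 examples per list. The 12 lists were written from general knowledge, as were 5 aliases of names. They hold myomiRs, candidates named by the study, other miRNAs of muscle differentiation, miR-17~92 and paralogs, let-7, Dlk1-Dio3, the miR-15/16 family, a proliferation list with miR-221 and miR-222, and markers of blood, epithelial, neural, and endothelial and smooth muscle cells. Lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison. Ratios with 1 to 3 reads in a group have an exact binomial interval on pooled reads.

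Seed sites were searched in the longest 3'UTR of Mrtfa annotated in GENCODE vM21 (GRCm38). Mature miRNA sequences were entered from general knowledge, and each one used was found in an annotated hairpin of the same name. The first set covered 127 of the 169 miRNAs tested (75.1%), short of the 80% needed. The missing names were then printed together with their bait fold changes, and 14 more sequences were added, for 141. Of these 14, 3 have a site (miR-324-3p, miR-466p-3p and miR-3103-3p), and all 3 were higher with the bait, so the test with the added sequences was not blind to the outcome. Median fold changes with and without a site were compared by 2-sided permutation over seed families (100000 resamples).

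The fits were tested on simulated data drawn from negative binomial counts with a dispersion of 0.25 and 200 changed miRNAs. Shares recovered are of the changed miRNAs that passed the filter, not of all 200. limma recovered 69.8% of 4-fold and 100% of 16-fold changes in the input. With the bait these were 71.9% and 97.3% in undifferentiated and 63.3% and 91.5% in differentiated cells, and in the interaction 7.41% and 84.6%. Of 2-fold changes it recovered 16.4, 9.09, 26.7 and 0%. It called 4 of 79 unchanged miRNAs in the interaction. limma was given the library sizes from which the reads were drawn, so these figures do not cover errors of scaling. The permutation of sites passed in 5 of 100 simulated sets without a shift and 99 of 100 with a shift of 2, after the number of sets was raised from 20, where 3 without a shift had passed. Those sets drew each miRNA independently, without the likeness within seed families that real fold changes show. Their recovery therefore does not give the power of the site test on the real data.

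Alternatives named with the plan were DESeq2, RLE factors, library totals, no filter, a filter of 10 CPM in 3 libraries, pseudocounts of 5 and 20, other libraries in the fit, each library left out, 8mer sites alone and the relation of input and eluate without myomiRs. Added after the data were seen were edgeR, TMM factors recomputed in the fit, mouse names alone, each kind of MS2 library alone, the shorter 3'UTR form, miRNAs of at least 50 CPM, the first set of sequences, the relation without the 2 miRNAs farthest from the median, bounds and counting ratios with each library of the higher group left out, and a block on the column suffix. The plan called the filter of 10 CPM in 3 libraries stricter, but it kept more miRNAs than filterByExpr in every comparison. A planned fit on miRNA features alone was void, since every name is that of a miRNA. The columns carry the suffixes none, 1 and 2, given here as letters A to C, which are not tied to the numbers in the titles. In differentiated input and MRTF-A eluates, libraries with the same suffix deviated together from their group means (Pearson r 0.314 to 0.636, all 3 pairs over 0.1), so they were taken as pairs from the data alone, although only 3 of the 6 correlated best with their own suffix. In no other comparison did every pair reach this. Sequence reads were not analysed here.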

Results

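C2C12 is a mouse myoblast line that fuses into multinucleate myotubes when serum is lowered. It was used here to ask which miRNAs the 3'UTR of MRTF-A retains before and after myogenic differentiation. MRTF-A, myocardin-related transcription factor A, is a coactivator of serum response factor and is encoded by the mouse gene Mrtfa. In miTRAP, miRNA trapping by RNA affinity purification, a bait RNA carrying MS2 hairpins is held on a resin through the MS2 coat protein, cell lysate is passed over it, and the RNA that stays bound is eluted. Small RNA was sequenced from 18 libraries in 6 groups of 3. The groups were input RNA, eluates of the MRTF-A 3'UTR bait and eluates of an MS2 control, each from undifferentiated cells and from cells after 7 days of differentiation. The labels do not say that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Libraries are called A, B and C within a group after the suffixes of their columns, which the labels do not tie to cultures.

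The table listed 2042 miRNA names, 1908 of mouse and 134 of human, and 1604 of them had a read in some library. Whole reads recovered from the normalised values summed to 4696187. Inputs held 294112 to 860828 reads each, MRTF-A eluates 107165 to 544504 and MS2 control eluates 15562 to 39695, so the control was the shallowest kind of library. A read was worth 1.66 units in the deepest library and at most 34.3, in differentiated MS2 library B. Units are CPM, reads scaled to an effective library size, and the values of a library need not sum to the nominal total because that size differs from the read total. Values are means ± SD over n = 3 libraries, log2 fold changes carry a standard error, and each adjusted p comes from limma over all miRNAs tested unless another tool is named. Fold changes were taken on the log2(CPM + 10) scale, which understates changes of low miRNAs. Against a group with 0 reads a fold is given as a lower bound, from 3 reads per library. Such bounds and all counting intervals cover counting error only.

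The 3 kinds of library differed in which miRNAs took most reads. miR-21a-5p, a miRNA abundant in many proliferating cells, took 44.3 ± 7.88% of the reads of undifferentiated input and 16.7 ± 1.54% of differentiated input. With the MRTF-A bait, miR-31-5p took 60.3 ± 6.95% of the reads from undifferentiated cells and 9.45 ± 1.27% from differentiated cells, where the muscle miRNA miR-1a-3p took 32.9 ± 1.82%. miR-34c-5p, a p53-responsive miRNA, took 7.70 ± 1.44% and 6.74 ± 1.32% of these eluates, and let-7f-5p 6.86 ± 2.90% and 8.59 ± 1.14%. In the MS2 control miR-6244 led all 3 differentiated libraries (40.7 ± 6.41%) but only undifferentiated library A (55.2%, against 10.46% in B and 20.0% in C, mean 28.6 ± 23.6%). miR-615-3p took 28.4 ± 4.82% of the undifferentiated and 24.4 ± 8.91% of the differentiated control. miR-5099 took 20.8 ± 18.2% of the undifferentiated control and led library B (38.3%).

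**Figure D1:**
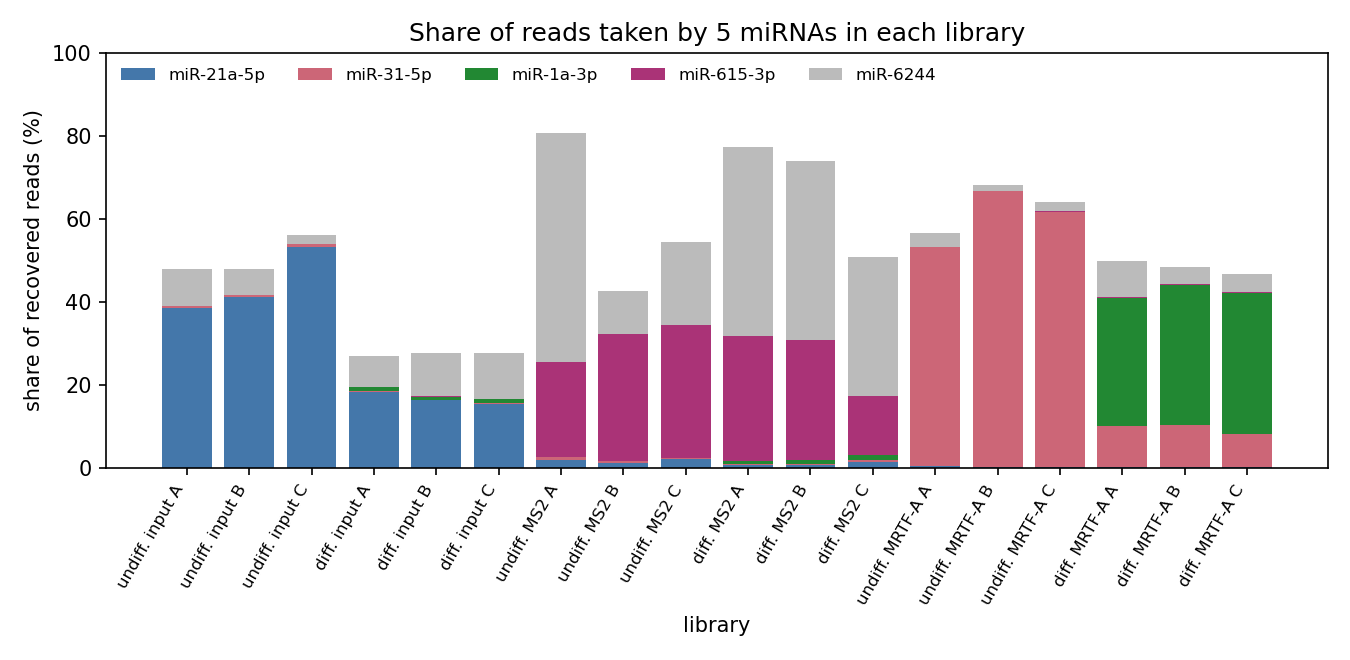
Stacked bars give the share of recovered reads (%) taken by miR-21a-5p, miR-31-5p, miR-1a-3p, miR-615-3p and miR-6244 in each of the 18 libraries. miR-31-5p and miR-1a-3p fill much of the MRTF-A eluates, miR-615-3p fills much of the MS2 control, and miR-6244 much of its differentiated libraries and of undifferentiated library A.

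Input libraries show how the miRNAs of the cells changed with differentiation. The 5 largest rises were those of myomiRs, which are expressed mainly in striated muscle. miR-1a-3p was at 7069 ± 609.6 CPM in differentiated input and at 0 reads in undifferentiated input, at least 945-fold higher (9.46 ± 0.31, adjusted p = 3.79e-11). miR-133a-3p rose from 605 ± 552 to 40632 ± 9089 CPM (6.48 ± 0.56, adjusted p = 2.52e-06). miR-206-3p, which is specific to skeletal muscle, rose from 120.3 ± 46.8 to 1298 ± 175 CPM (3.38 ± 0.35, adjusted p = 8.55e-06). The largest fall was that of miR-7a-5p, from 1729 ± 554 to 12.7 ± 8.61 CPM (-6.27 ± 0.38, adjusted p = 6.07e-08), and miR-92a-3p of the growth-promoting miR-17~92 cluster fell from 55651 ± 14231 to 6309 ± 2078 CPM (-3.17 ± 0.36, adjusted p = 1.32e-05).

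All 8 tested names of the myomiR list rose (8 when adjusted over the list alone, camera adjusted p = 1.71e-10, adjusted p = 0.108 with an estimated correlation). The others were miR-133b-3p (4.46 ± 0.62), miR-499-5p (0 undifferentiated reads, at least 25.3-fold), miR-208b-3p (0 reads, at least 5.26-fold), and miR-486-5p with miR-3107-5p (2.83 ± 0.32 and 2.84 ± 0.32), which have the same mature sequence. This pair is therefore 1 molecule measured under 2 names and counts as 2 in every number given for the myomiR and candidate lists. miR-133a-3p and miR-133b-3p are near-identical, so their reads may be split between the names. Of the candidates that the study itself picked, miR-1a-3p, miR-206-3p, miR-24-3p and the miR-486 pair, 4 of 5 names rose (4 when adjusted over the list alone, adjusted p = 1.25e-05, adjusted p = 0.140 with an estimated correlation). That list was chosen on these samples and is not independent evidence. miR-24-3p, its other member, was 0.50 ± 0.34 (adjusted p = 0.223), and passed the threshold under each of the 5 other scalings and tests, at up to 1.21. Outside the lists, miR-1b-5p (0 reads, at least 7.59-fold), miR-1843a-5p (2.60 ± 0.33), miR-328-3p (2.36 ± 0.37) and miR-362-3p (2.29 ± 0.36) were among the 12 largest rises. miR-1b-5p is complementary to miR-1a-3p over its whole length. As the strand handling of reads is not given, it may not be a separate molecule. Among the 12 largest falls were also miR-27a-5p (-4.51 ± 0.43), miR-31-3p (-3.73 ± 0.42), miR-125a-3p (-3.70 ± 0.39), miR-125b-1-3p (-3.04 ± 0.35) and miR-222-5p (-2.90 ± 0.34).

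Of 25 other miRNAs linked to muscle differentiation, 6 rose and 4 fell (5 and 3 when adjusted over the list alone, camera adjusted p = 0.0125, adjusted p = 0.596 with an estimated correlation). miR-128-3p (2.84 ± 0.33), miR-181a-5p (1.72 ± 0.34) and miR-378a-3p (1.58 ± 0.33) rose, while miR-214-3p fell by 1.80 on the log2 scale. In the miR-17~92 cluster and its paralogs 9 of 10 fell and miR-363-3p rose (9 and 1 over the list alone, adjusted p = 0.0532), with miR-18a-5p at -3.06 ± 0.41 and miR-20a-5p at -2.58 ± 0.40. In the let-7 family 7 of 10 fell (8 over the list alone, adjusted p = 0.0645), let-7i-5p the most (-2.82 ± 0.33). All 5 of the proliferation list, which holds miR-221 and miR-222, fell, among them miR-222-3p (-2.70 ± 0.36), miR-31-5p (-2.31 ± 0.31) and miR-21a-5p (-1.91 ± 0.39), with 5 over the list alone, adjusted p = 0.0447, and adjusted p = 0.596 with an estimated correlation. Of 4 tested miRNAs of the miR-15/16 family, miR-322-5p rose and 2 fell (the same numbers over the list alone, adjusted p = 0.985). Among the marker lists of other cell types, neural miR-128-3p rose and miR-129-5p and miR-9-5p fell (3 tested, the same over the list alone, adjusted p = 0.939). The only blood marker tested was miR-486-5p, which is also a myomiR. With limma none of the 3 endothelial and smooth muscle (adjusted p = 0.380), 2 epithelial and 1 Dlk1-Dio3 miRNAs tested passed, over all miRNAs or over the list alone, and 0 had an unadjusted p under 0.05, while DESeq2 and edgeR each called 2, 1 and 0 of them.

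Of 313 miRNAs tested 50 rose and 145 fell, and the median of all tested was -0.64. This split moved with the scaling. It was 87 up and 91 down with DESeq2 (median -0.13), 86 and 95 with edgeR (-0.11), 91 and 92 with RLE factors (-0.07), 75 and 106 with library totals (-0.24, or -0.75 with miR-21a-5p left out of the totals, chosen after seeing the data), and 88 and 90 with TMM factors of the 6 inputs alone (-0.08). All 6 of these scalings and tests called 136 miRNAs the same way, 50 up and 86 down, which include miR-1a-3p, miR-133a-3p, miR-206-3p, miR-7a-5p and miR-92a-3p. Relative to the median, miR-1a-3p stood at 10.10, miR-133a-3p at 7.12, miR-7a-5p at -5.63 and miR-92a-3p at -2.53. With the TMM factors of the inputs the falls numbered 3 of 10 in let-7, 6 of 10 in the miR-17~92 list, 4 of 5 in the proliferation list and 0 of 4 in the miR-15/16 family, while 14 of the 25 other differentiation miRNAs and 2 of the 3 endothelial and smooth muscle miRNAs rose. The authors' deposited table listed 152 at a false discovery rate under 0.05, 35 up and 117 down, of which 134 were called here with the same sign.

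**Figure D2:**
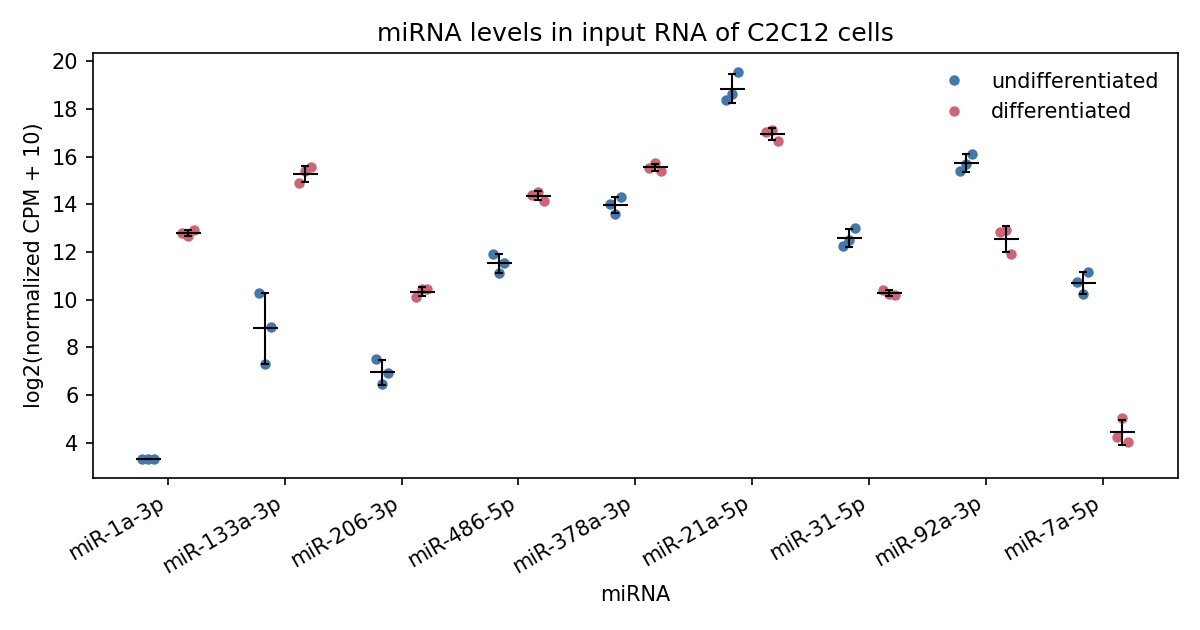
Each point is the log2(CPM + 10) of a miRNA in an input library of undifferentiated (blue) or differentiated (red) cells, with mean and SD bars over the 3 libraries. miR-1a-3p had 0 reads in the undifferentiated inputs, and miR-7a-5p fell from 1729 to 12.7 CPM.

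Eluates of the MRTF-A bait were compared with the MS2 control to find the miRNAs retained by the 3'UTR. In undifferentiated cells miR-31-5p, a miRNA known to repress Myf5 in quiescent satellite cells, was at 1303190 ± 570601 CPM with the bait and 2996 ± 1387 with the control (8.77 ± 0.41, adjusted p = 4.79e-09). miR-140-5p, best known from cartilage, was at 72327 ± 13645 against 203 ± 143 CPM (8.73 ± 0.52, adjusted p = 3.13e-08). Also higher were miR-34c-5p (7.70 ± 0.37, adjusted p = 5.09e-09), let-7g-5p (7.01 ± 0.57, adjusted p = 2.72e-07) and miR-199a-5p, encoded opposite introns of the Dnm genes (6.95 ± 0.31, adjusted p = 4.79e-09). In the other direction, miR-615-3p, encoded in the Hoxc cluster, was at 2371 ± 397 with the bait and 154602 ± 11106 with the control (-6.03 ± 0.45, adjusted p = 1.68e-07), and miR-199a-3p, the other arm of the miR-199a hairpin, was lower (-3.72 ± 0.43, adjusted p = 5.92e-06).

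Several of the largest values rested on very few control reads. miR-3103-3p had 3 control reads and a ratio of 342 (95% counting interval 117 to 1661), or 213 without undifferentiated MRTF-A library B, and miR-34b-5p had 3 and a ratio of 154 (95% counting interval 52.5 to 749). With 1 control read each, the ratio was 334 (95% counting interval 59.7 to 13223) for miR-374b-5p and 225 (95% counting interval 40.1 to 8912) for miR-7649-3p. miR-185-5p had 0 control reads and was at least 23.4-fold higher with the bait. With 0 reads in the bait eluates, miR-99a-5p was at least 4.32-fold and hsa-miR-6509-3p at least 29.9-fold lower, the latter only 8.12-fold without undifferentiated MS2 library A. miR-423-3p was lower as well (-4.45 ± 0.35).

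Of the study's own candidates, chosen on these samples and so no independent evidence, 4 of 5 names (the miR-486 pair again as 2) were higher with the bait in undifferentiated cells (4 when adjusted over the list alone, adjusted p = 0.211). miR-24-3p, a miRNA that promotes exit from the cell cycle, was at 4.71 ± 0.43. miR-206-3p had 1 control read and a ratio of 117 (95% counting interval 20.8 to 4648), or 64.7 without undifferentiated MRTF-A library A. miR-486-5p (2.25 ± 0.41) and miR-3107-5p (2.08 ± 0.37) did not pass with library totals, at 0.37 and 0.20. miR-1a-3p, with 10 bait and 2 control reads, was at 1.22 ± 0.70 (adjusted p = 0.142), and reached 2.19 (adjusted p = 0.00226) without undifferentiated MS2 library A. Of the myomiRs 3 of 6 were higher (3 over the list alone, adjusted p = 0.690), and miR-133a-3p (-0.59 ± 0.82) and miR-133b-3p (-0.09 ± 0.53) were not. The let-7 family was higher as a group, 7 of 9 (8 over the list alone, median 4.75, adjusted p = 0.00949, adjusted p = 0.776 with an estimated correlation), and 7 were higher and 1 lower with library totals. In the other differentiation list 8 of 18 were higher and 4 lower (8 and 5 over the list alone, adjusted p = 0.690), against 5 and 7 with library totals, and in the proliferation list 1 of 4 was higher and 1 lower (the same over the list alone, adjusted p = 0.690), against 1 and 3. miR-486-5p was the only blood marker tested, 1 of 2 miR-15/16 members was lower, and with limma none of 2 miR-17~92, 1 neural and 1 endothelial and smooth muscle miRNAs passed (0 at an unadjusted p under 0.05, while DESeq2 and edgeR each called 1, 0 and 1), with the same numbers over each list alone. No Dlk1-Dio3 or epithelial member was tested.

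Together 102 of 169 miRNAs tested differed in undifferentiated cells, 73 higher and 29 lower with the bait, around a median of 1.16. Relative to that median miR-31-5p was at 7.61, miR-140-5p at 7.57, miR-24-3p at 3.55 and miR-615-3p at -7.19. The split was 55 higher and 63 lower with library totals (median -0.25), 73 and 46 with DESeq2 (0.73) and 71 and 45 with edgeR (0.66), while the medians were 0.84 with RLE and 0.98 with TMM factors of the eluates. All 6 called 84 the same way, 55 higher and 29 lower. The MS2 control libraries stood apart in 2 kinds, with 0.0900 to 0.115% of reads on human-named miRNAs in 3 and 0.755 to 0.930% in the other 3 (differentiated A and B, undifferentiated A). With either kind alone, chosen after seeing the data, 98 and 100 of the 102 were still tested, and all of these kept their sign. The latter kind leaves 1 MS2 library in this state. The kept signs decide little, as the fits share the bait libraries and calls without control reads cannot change sign. How many calls hold cannot be told from these fits, as each leaves 1 MS2 library in a state. The authors' deposited table listed 119, 92 higher and 27 lower, and 91 of the 102 were among them with the same sign.

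In differentiated cells miR-1a-3p, the most abundant miRNA of the bait eluates, was at 568026 ± 39253 CPM with the bait against 5764 ± 1048 with the control (6.63 ± 0.70, adjusted p = 2.82e-06). miR-206-3p, which shares the seed of miR-1a-3p, was at 19079 ± 813 against 272 ± 27.6 CPM (6.08 ± 0.58, adjusted p = 1.13e-06). let-7g-5p (6.96 ± 0.57, adjusted p = 3.47e-07), let-7a-5p (6.19 ± 0.34, adjusted p = 3.67e-08), miR-140-5p (6.60 ± 0.52, adjusted p = 2.62e-07), miR-31-5p (6.41 ± 0.41, adjusted p = 6.12e-08) and miR-34c-5p (6.34 ± 0.37, adjusted p = 3.67e-08) were again far above the control. miR-615-3p (-5.96 ± 0.45, adjusted p = 2.06e-07), miR-690 (-5.14 ± 0.46, adjusted p = 6.09e-07), miR-199a-3p (-4.60 ± 0.43, adjusted p = 8.85e-07) and miR-199b-3p (-4.41 ± 0.41, adjusted p = 9.32e-07) were lower, the last pair being 1 mature sequence under 2 names and so 1 measurement.

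With 0 control reads, miR-221-5p was at least 22.9-fold (758, 943 and 11 reads in bait libraries A, B and C), miR-296-5p at least 10.3-fold and miR-185-5p at least 8.03-fold higher in the differentiated bait eluates. miR-34b-5p had 3 control reads and a ratio of 97.2 (95% counting interval 33.2 to 472), and hsa-miR-6509-3p had 3 bait reads and a ratio of control to bait of 567 (95% counting interval 192 to 2771). Its control reads, 111, 104 and 11 in MS2 libraries A, B and C, follow the 2 kinds of MS2 library, which the interval does not cover, and the ratio was 876 without library C. All 5 names of the study's candidates, with the miR-486 pair as 2, were higher (5 over the list alone, adjusted p = 0.137), which is again no independent evidence, with miR-24-3p at 4.94 ± 0.43. miR-486-5p (2.37 ± 0.41) and miR-3107-5p (2.27 ± 0.37) again missed the threshold with library totals, at 0.92 and 0.82. Of the myomiRs 5 of 6 were higher (5 over the list alone, adjusted p = 0.343). miR-133a-3p (2.87 ± 0.82, adjusted p = 0.00654) did not pass with library totals, at 1.43, or with only the MS2 libraries of few human-named reads (2.28), and miR-133b-3p was at 0.02 ± 0.53. All 9 let-7 members were higher (9 over the list alone, median 5.03, adjusted p = 0.00699, adjusted p = 0.532 with an estimated correlation). In the other differentiation list 11 of 18 were higher and 3 lower (11 and 3 over the list alone, adjusted p = 0.865), with miR-199a-5p at 5.76 ± 0.31 and miR-34a-5p at 5.16 ± 0.39. In the proliferation list miR-31-5p was higher and miR-21a-5p and miR-222-3p were lower (4 tested, the same over the list alone, adjusted p = 0.343). The blood marker miR-486-5p was higher, and with limma none of 2 miR-17~92, 2 miR-15/16, 1 neural and 1 endothelial and smooth muscle miRNAs passed, over all miRNAs or over the list alone (0 at an unadjusted p under 0.05, while DESeq2 and edgeR each called 0, 2, 0 and 1).

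In differentiated cells 134 of 169 miRNAs differed, 97 higher and 37 lower, around a median of 2.37, and relative to it miR-1a-3p was at 4.26, miR-31-5p at 4.04 and miR-615-3p at -8.32. The median was 1.47 with DESeq2, 1.38 with edgeR, 1.78 with RLE, 2.34 with TMM factors of the eluates and 1.18 with library totals, where 73 were higher and 49 lower. All 6 called 103 the same way, 68 higher and 35 lower. With the MS2 libraries of few human-named reads alone, of which this state has 1, 130 of the 134 were still tested, and with the other kind 132. All of these kept their sign, which higher calls without control reads could not lose, and how many calls hold cannot be told from such fits. The authors' deposited table listed 160, 108 higher and 52 lower, and shared 124 of the 134 calls. Both states had 71 higher and 27 lower miRNAs in common, where independent lists would share 41.9 and 6.35. The lists are not independent, since both comparisons came from the same fit, with shared variances, filter and scaling. The excess over these numbers is therefore no measure of replication. The fold changes of both states, which share no libraries, had a Pearson r of 0.864 across the 169 miRNAs, which are not independent replicates. miR-22-3p, chosen here after its values were seen, was the only miRNA called in opposite directions (-1.01 ± 0.30 undifferentiated, 1.04 ± 0.30 differentiated). Its differentiated value ran from -0.40 to 1.06 over the 6 scalings and tests and was not called under all of them, so the reversal depends on the scaling.

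**Figure D3:**
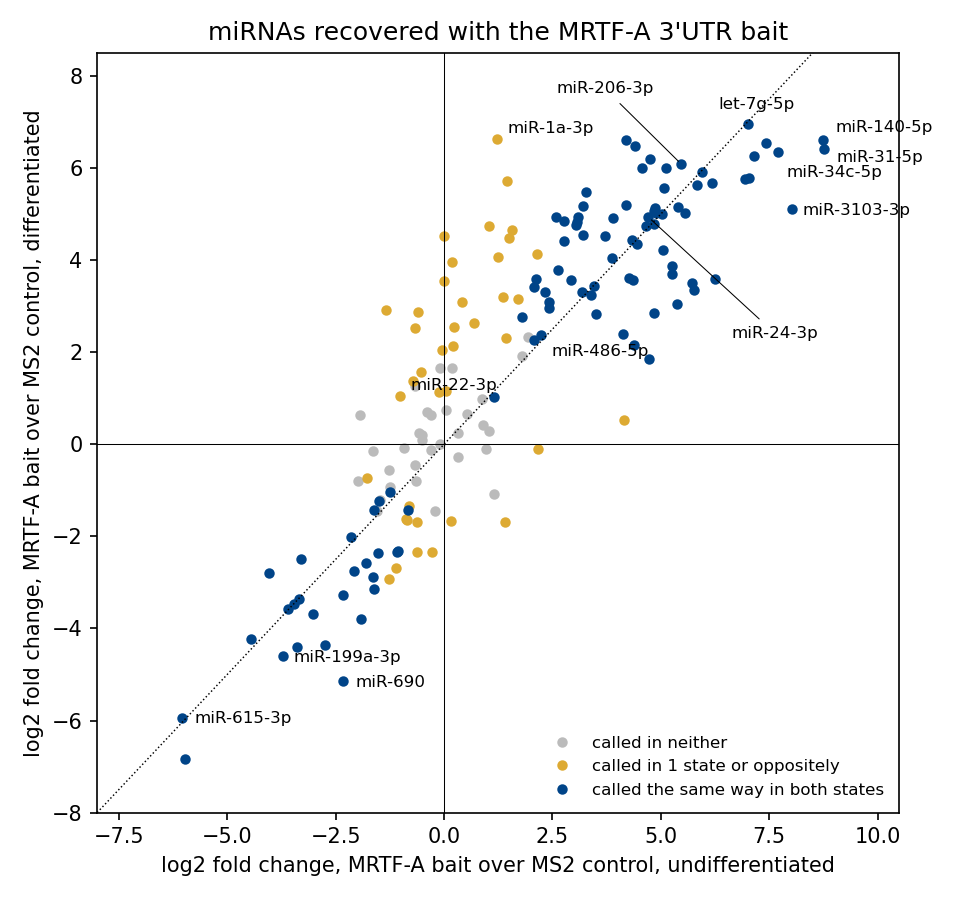
Each point is a miRNA, with its log2 fold change of MRTF-A bait over MS2 control in undifferentiated (x) and differentiated (y) cells, coloured by the states in which it was called, and the dotted line marks equal values. 71 miRNAs were higher in both states, and miR-1a-3p lies far above the line at 1.22 and 6.63.

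Whether retention by the bait differed between the states was tested as an interaction, the bait difference in differentiated cells minus that in undifferentiated cells. miR-1a-3p had the largest value (5.41 ± 0.99, adjusted p = 0.00761), on 10 undifferentiated bait reads and on 2 undifferentiated and 551 differentiated control reads. It had 0 reads in undifferentiated input. Its undifferentiated ratio of bait to control was 3.05 (95% counting interval 0.650 to 28.6), so its retention there could barely be measured. miR-1b-5p, from a hairpin opposite that of miR-1a-2 and complementary to miR-1a-3p, had 0 reads in both undifferentiated eluate groups. Its value (4.52 ± 0.55, adjusted p = 4.49e-04) therefore repeats its differentiated bait difference and measures no change of retention. miR-31-5p was negative (-2.35 ± 0.58, adjusted p = 0.0235). Its bait value fell from 1303190 to 164771 CPM while the control value was 2996 and 1916. It also fell in the input (-2.31), and its bait eluate was 7.63 above input in undifferentiated and 7.02 in differentiated cells. A fall of its level in the cells therefore cannot be told apart from a loss of retention. The other candidates showed no detectable difference, with miR-206-3p at 0.61 ± 0.82 (adjusted p = 0.667), miR-24-3p at 0.22 ± 0.61 (0.898), miR-486-5p at 0.12 ± 0.57 (0.955) and miR-3107-5p at 0.18 ± 0.52 (0.899).

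Further positive values were those of let-7d-3p (4.27 ± 1.29, adjusted p = 0.0481), miR-1839-5p (3.78 ± 0.92, adjusted p = 0.0235) and miR-378c (3.69 ± 0.93, adjusted p = 0.0241), and further negative ones those of miR-301b-3p (-2.87 ± 0.81, adjusted p = 0.0371), miR-690 (-2.80 ± 0.65, adjusted p = 0.0224), miR-3074-5p (-2.42 ± 0.61, adjusted p = 0.0241) and miR-466p-3p (-2.23 ± 0.43, adjusted p = 0.00956). Each of these except miR-690 had under 10 reads in a control group. miR-3074-5p is complementary to miR-24-3p over nearly its whole length, so it may not be a separate molecule. With each of the 12 eluates left out in turn, let-7d-3p, miR-378c and miR-301b-3p lost the call 9 times, miR-1839-5p and miR-3074-5p 4 times and miR-466p-3p 2 times. miR-378c and miR-466p-3p are among 7 of the 22 calls with 0 control reads in both states, so their values are the change of the bait eluate and measure nothing against the control. miR-690 was below the control in both states (-2.34 and -5.14). Its bait value was 36.7 in undifferentiated and 61.8 CPM in differentiated cells while the control went from 234 to 2416 CPM, so it is no loss of retention by the bait. miR-133a-3p was at 3.46 ± 1.16 (adjusted p = 0.0646), and passed with DESeq2 (3.21), with a pseudocount of 20 (3.25), and without undifferentiated MS2 library A (4.24, adjusted p = 0.0360) or undifferentiated MRTF-A library C (4.42, adjusted p = 0.0219). miR-133b-3p was at 0.10 ± 0.74. Of the lists, 1 of 6 myomiRs (2 over the list alone, adjusted p = 0.202), 1 of the 5 candidates chosen on these samples (1, 0.309), 1 of 18 other differentiation miRNAs (1, 0.503) and 2 of 9 let-7 members (3, 0.188) were called positive, and 1 of 4 in the proliferation list negative (1, 0.188). With limma none passed of 2 miR-17~92, 2 miR-15/16, 1 blood, 1 neural and 1 endothelial and smooth muscle miRNAs, over all miRNAs or over the list alone, where 1 miR-17~92 member had an unadjusted p under 0.05 and DESeq2 and edgeR called 0.

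The interaction called 22 of 169 miRNAs, 14 positive and 8 negative, around a median of 0.14. The split was 8 positive and 13 negative with DESeq2 (median -0.28), 0 and 3 with edgeR (-0.26), 11 and 19 with RLE factors (-0.15), 9 and 5 with library totals (0.54) and 14 and 7 with TMM factors of the eluates (0.40), and only miR-690, whose value comes from the rise of the control, was called under all 6, though not with no filter, with either kind of MS2 library alone, or without differentiated MS2 library B or undifferentiated MS2 library C. miR-1a-3p ran from 4.65 to 5.54 over the 6 and miR-1b-5p from 3.09 to 5.03, and both missed the threshold with edgeR alone. The other calls named above also missed it with edgeR, among them miR-31-5p, which did so with no filter and with the MS2 libraries of many human-named reads as well (-1.63). The count fell to 8 without differentiated MRTF-A library B, 14 without differentiated MRTF-A library C, 4 without differentiated MS2 library B and 5 without undifferentiated MS2 library C. Without them miR-31-5p was at -2.45, -2.17, -2.23 and -2.15 (adjusted p = 0.0513, 0.0526, 0.0543 and 0.0522), while miR-1a-3p and miR-1b-5p passed whichever of the 12 eluates was left out (highest adjusted p 0.0347 and 0.00529). As miR-1a-3p and miR-1b-5p may hold reads of the same molecule, they do not count as independent results. With either kind of MS2 library alone, each of which leaves 1 MS2 library in a state, 6 and 8 of the 22 were called again.

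Bait eluates of both states were also compared directly. miR-1a-3p rose from 44.6 ± 41.3 to 568026 ± 39253 CPM (13.60 ± 0.70, adjusted p = 1.45e-08), miR-133a-3p also rose (9.48 ± 0.82, adjusted p = 4.04e-06), and miR-206-3p went from 834 ± 766 to 19079 ± 813 CPM (4.87 ± 0.58, adjusted p = 3.42e-05). miR-31-5p fell from 1303190 ± 570601 to 164771 ± 33623 CPM (-2.92 ± 0.41, adjusted p = 1.38e-04). With 0 undifferentiated reads, miR-1b-5p was at least 137-fold and miR-128-3p at least 11.2-fold higher, and miR-133b-3p, with 1 read, had a ratio of 101 (95% counting interval 18.04 to 4018). miR-7649-3p (-3.37 ± 0.59) and miR-5128 (-3.31 ± 0.62) fell, and so did miR-6999-3p (-3.58 ± 0.81) except with library totals (adjusted p = 0.0519). miR-5099 (-2.94 ± 1.06, adjusted p = 0.0448) did not pass with library totals (-2.69), TMM factors of the eluates (-2.80), no filter, the filter of 10 CPM in 3 libraries or a pseudocount of 5, nor without differentiated MRTF-A library A (adjusted p = 0.0555) or C (0.194), or undifferentiated library B (0.181) or C (0.106).

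All 6 tested myomiRs rose in the eluates (6 over the list alone, camera adjusted p = 1.01e-05, adjusted p = 0.0152 with an estimated correlation), and 4 of the 5 candidates chosen on these samples did (4, 5.73e-04, adjusted p = 0.117 with an estimated correlation), with miR-486-5p at 3.78 ± 0.41, miR-3107-5p at 3.73 ± 0.37 and miR-24-3p at 0.88 ± 0.43 (adjusted p = 0.121). Of the other differentiation list 8 of 18 rose (8 over the list alone, adjusted p = 0.00944, adjusted p = 0.234 with an estimated correlation), among them miR-22-3p (2.96 ± 0.30), miR-378a-3p (3.36 ± 0.37) and miR-181a-5p (3.32 ± 0.56). In the proliferation list miR-31-5p and miR-21a-5p fell (-1.30 ± 0.30 for the latter), 2 of 4 (3 over the list alone, adjusted p = 0.00869, adjusted p = 0.133 with an estimated correlation). In let-7 1 of 9 rose and 1 fell (the same over the list alone, adjusted p = 0.933), 1 of 2 miR-17~92 members fell (2 over the list alone), and 1 of 2 miR-15/16 members, blood miR-486-5p, neural miR-128-3p and endothelial and smooth muscle miR-143-3p rose (the same over each list alone). In total 65 of 169 changed, 40 up and 25 down, around a median of 0.33, and relative to it miR-1a-3p was at 13.27 and miR-31-5p at -3.25. The split was 37 and 43 with both DESeq2 (median -0.12) and edgeR (-0.10), 30 and 37 with RLE (0.00), and 32 and 13 with library totals (0.49), while TMM factors of the eluates gave a median of 0.47. All 6 called 37, 24 up and 13 down. Across 141 miRNAs tested in both, which are not independent replicates, the change in the eluate followed that in the input with Pearson r = 0.858 and Spearman rho = 0.760, and 68.1% had the same sign. Without the myomiRs r was 0.754.

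Bait eluates were also compared with the input, to show which miRNAs stood above their level in the cells. The MS2 control has no part in this, so it cannot assign an enrichment to the 3'UTR. miR-615-3p, far below the control, still took 0.117% of undifferentiated bait eluate reads against 0.0346% of input reads. In differentiated cells these shares were 0.136 and 0.0214%. miR-31-5p was 7.63 ± 0.34 above input in undifferentiated and 7.02 ± 0.34 in differentiated cells (adjusted p = 3.39e-11 and 5.79e-11), and miR-140-5p 9.54 ± 0.48 and 8.90 ± 0.48 (7.72e-11 and 8.67e-11). miR-34c-5p was higher by 6.57 ± 0.35 and 6.72 ± 0.35, and miR-199a-5p by 6.65 ± 0.33 in differentiated cells. miR-1a-3p took 0.947% of differentiated input reads and was above input in the eluate (6.33 ± 0.61, adjusted p = 1.44e-07). The abundant cellular miR-21a-5p was far below input in both states, at -6.48 ± 0.31 and -5.87 ± 0.31 (adjusted p = 5.73e-11 and 8.52e-11), and miR-362-3p was at -6.77 ± 0.45 and -8.94 ± 0.45, on 2 undifferentiated bait reads (ratio of input to bait 255, 95% counting interval 70.6 to 2109).

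miR-3103-3p was 8.58 ± 0.71 above undifferentiated input, and with 1 read in differentiated input had a ratio of 17673 (95% counting interval 3171 to 698116). miR-7649-3p had 1 undifferentiated input read and a ratio of 1799 (95% counting interval 321 to 71259.8). miR-770-3p, with 0 bait reads, was at least 26.6-fold lower than undifferentiated input. miR-7680-5p was lower in both states (-6.33 ± 0.75 and -6.37 ± 0.75), and so was miR-7680-3p, at -6.59 ± 0.77 in undifferentiated cells and, on 2 bait reads, with a ratio of input to bait of 766 (95% counting interval 212 to 6324) in differentiated cells, where miR-30a-5p was lower too (-5.67 ± 0.37). miR-206-3p (2.38 ± 0.53 undifferentiated, 3.88 ± 0.53 differentiated) and miR-24-3p (1.94 ± 0.41 and 2.32 ± 0.41) were above input, except with library totals for miR-206-3p in undifferentiated cells (1.48) and for miR-24-3p in both states (1.01 and 1.13). miR-1a-3p had 0 reads in undifferentiated input and only 6, 2 and 2 in the bait libraries, a bound of 5.96-fold that fell to 2.80 without bait library A, and also did not pass with library totals. miR-133b-3p was below input (-5.82 ± 0.65 and -5.26 ± 0.65), on 1 bait read in undifferentiated cells (ratio of input to bait 245, 95% counting interval 43.9 to 9679.5, or 143 without undifferentiated input library A). miR-133a-3p was at -4.52 ± 0.83 and -1.53 ± 0.83, the latter with adjusted p = 0.117, though DESeq2, edgeR and library totals called it lower. miR-499-5p was lower in differentiated cells, on 2 bait reads (ratio of input to bait 68.3, 95% counting interval 18.7 to 567), and had 0 reads in both undifferentiated groups. miR-486-5p and miR-3107-5p did not pass in either state, at -0.16 ± 0.37 and -0.11 ± 0.34 in undifferentiated and 0.78 ± 0.37 and 0.78 ± 0.34 in differentiated cells, and their sign moved with the scaling, from -1.08 to 1.26 for miR-486-5p in undifferentiated cells. With the column suffix as a block, chosen after seeing the data, both names of this molecule passed in differentiated cells (0.78, adjusted p = 0.0475 and 0.0484).

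Against input, let-7 was enriched, with 7 of 10 higher and 1 lower in undifferentiated cells (7 and 1 over the list alone, camera adjusted p = 0.0191, adjusted p = 0.538 with an estimated correlation) and 8 of 10 higher in differentiated cells (8, 0.00409, adjusted p = 0.401 with an estimated correlation). With library totals these were 4 and 2, and 8 and 1. The miR-17~92 list was depleted, 10 of 10 lower and 7 of 10 lower (the same over the list alone, 0.0191 and 0.0212, adjusted p = 0.292 and 0.154 with an estimated correlation), with miR-25-3p at -5.08 ± 0.68 and -5.37 ± 0.68. All 3 endothelial and smooth muscle miRNAs were lower in both states (3 over the list alone, 0.109 and 0.0467, the latter adjusted p = 0.154 with an estimated correlation), among them miR-143-3p (-4.36 ± 0.29 and -3.16 ± 0.29). Of the other differentiation list 5 of 23 were higher in each state and 17 and 12 lower (the same over the list alone, 0.109 and 0.0875), and of the proliferation list 1 of 4 was higher and 3 and 2 lower (the same, 0.639 and 0.677). Of 7 myomiRs 2 were higher and 2 lower in each state (2 and 2, then 3 and 2 over the list alone, 0.732 and 0.971). Of the 5 candidates chosen on these samples 3 were higher in each state (3 and 4 over the list alone, 0.149 and 0.0625), but 0 in undifferentiated cells with library totals. With the block 5 were higher in differentiated cells (adjusted p = 0.0496, adjusted p = 0.342 with an estimated correlation). Of 3 miR-15/16 members 2 were lower in undifferentiated and 0 in differentiated cells with limma (1 at an unadjusted p under 0.05, 2 called by DESeq2 and by edgeR, 0.732 and 0.677), of 4 neural miRNAs 3 were lower and then 1 higher and 1 lower (0.367 and 0.677), and epithelial miR-192-5p was lower in both states, with the same numbers over each list alone except 2 lower neural miRNAs in differentiated cells. The blood marker miR-486-5p and the only Dlk1-Dio3 member tested did not pass with limma (0 at an unadjusted p under 0.05), while DESeq2 and edgeR called miR-486-5p in undifferentiated cells.

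Against undifferentiated input 209 of 305 miRNAs differed, 71 higher and 138 lower, around a median of -1.04. The split was 112 and 99 with DESeq2 (median 0.00), 108 and 95 with edgeR (-0.17), 91 and 96 with RLE (-0.17) and 50 and 159 with library totals (-1.68), and all 6 called 138, 50 higher and 88 lower. Against differentiated input 189 differed, 95 higher and 94 lower, around -0.14, with 69 and 125 under library totals (-0.83), and all 6 called 161, 68 higher and 93 lower. DESeq2, edgeR and RLE gave medians of -0.19, -0.22 and -0.19 there. Relative to the medians miR-31-5p was at 8.66 and 7.16, miR-140-5p at 10.58 and 9.04, and miR-21a-5p at -5.44 and -5.72. The authors' deposited table listed 248 and 291 at a false discovery rate under 0.05, and 201 of the 209 and 189 of the 189 were among them with the same sign.

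Seed matches in the annotated mouse 3'UTR were set against the fold changes of bait over control. The 3'UTR of Mrtfa lies on chromosome 15 of GRCm38, from 81012281 to 81013284 on the minus strand, and is 1004 nucleotides long in the longest annotated form. miR-1a-3p and miR-206-3p share a 7mer-m8 site, pairing with miRNA positions 2 to 8, at 81012498 to 81012504 (3'UTR positions 781 to 787). miR-140-5p has such a site at 81012859 to 81012865 (420 to 426). miR-486-5p and miR-3107-5p, the same sequence, have a 7mer-A1 site, pairing with positions 2 to 7 opposite a following A, at 81012699 to 81012705 (580 to 586). miR-31-5p has a 7mer-A1 site at 81012281 to 81012287 (998 to 1004), the last bases of the longest form, which the shorter annotated form of 994 nucleotides lacks. miR-24-3p, miR-34c-5p, miR-199a-5p and the let-7 family had no 7mer or 8mer site. miR-21a-5p has a 7mer-m8 site at 81013117 to 81013123 (162 to 168). It was below the control in undifferentiated (-0.82 ± 0.30) and in differentiated cells (-1.42 ± 0.30). The labels do not say from which species or form the bait was made.

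Of 141 tested miRNAs with a known mature sequence, 25 had a site. In undifferentiated cells 18 of the 25 and 47 of the other 116 were higher with the bait, and in differentiated cells 21 and 69. The median log2 fold change was 3.19 with and 1.00 without a site in undifferentiated cells, a difference of 2.19 (2-sided permutation test over seed families, p = 0.0622, adjusted over both states 0.112). In differentiated cells the medians were 4.42 and 2.54, a difference of 1.88 (permutation p = 0.112, adjusted 0.112), so neither difference passed the threshold. The 25 include 3 whose sequences were added after bait values had been seen, and without all 14 sequences added then the differences were 1.27 (permutation p = 0.362) and 1.39 (0.198), over 75.1% of the miRNAs tested.

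**Figure D4:**
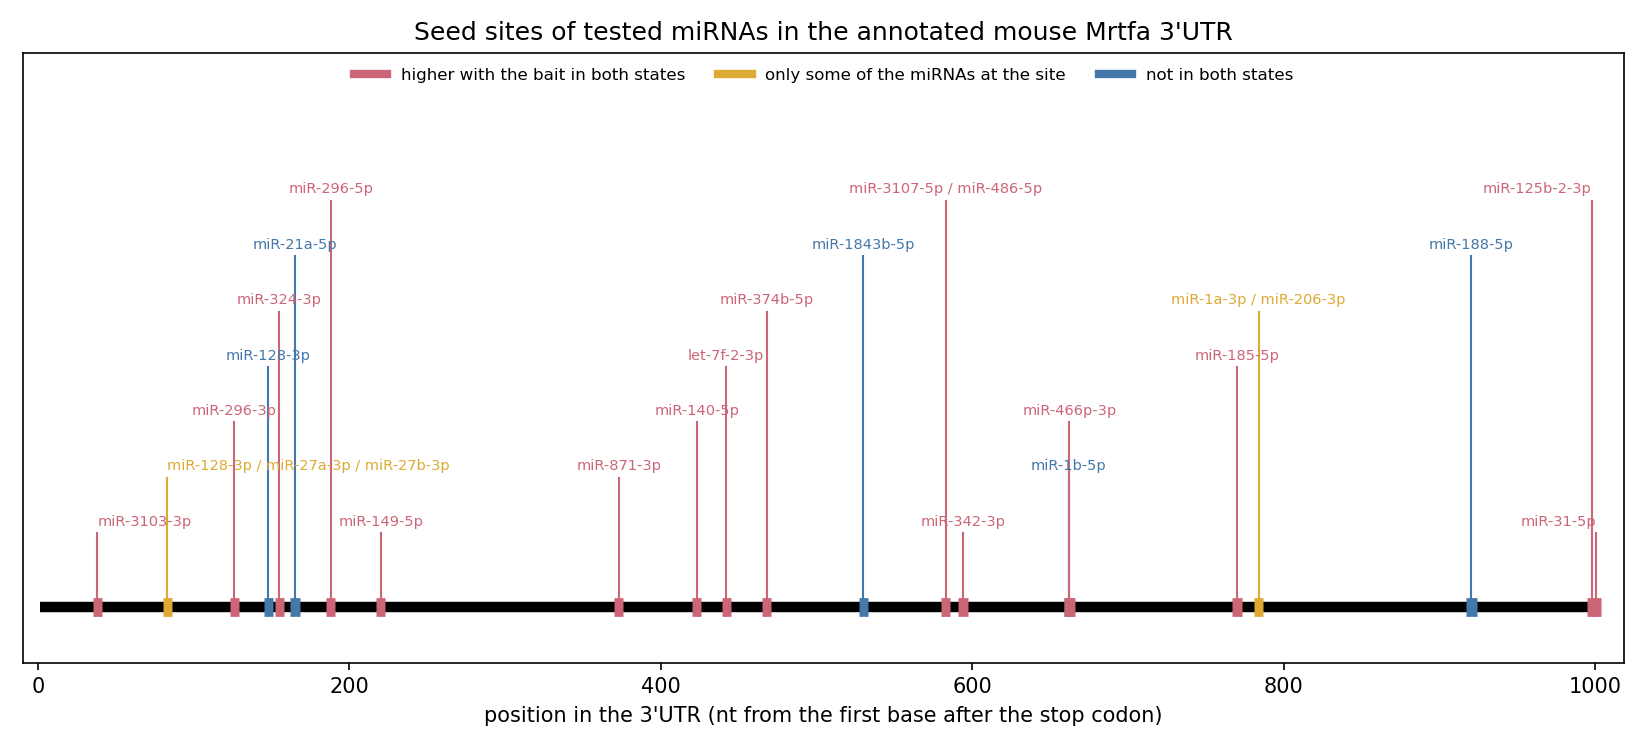
The 1004-nucleotide annotated mouse Mrtfa 3'UTR is drawn to scale from the first base after the stop codon, with the seed sites of tested miRNAs coloured by whether the miRNAs at the site were higher with the bait in both states. miR-1a-3p and miR-206-3p share the site at 781 to 787.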

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

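Tests chosen after the result was seen were both of the input split, the comparison of bait-enriched miRNAs with the input and its simulated draws, the fits with each kind of MS2 library, and the conditions of a control read and of at least 2 MS2 libraries per state set on them.

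A difference between groups singled out 10 miRNAs. They have the 5 largest positive and 5 largest negative changes of the bait difference among the 22 called, not among all tested. miR-1a-3p (5.41), miR-1b-5p (4.52), let-7d-3p (4.27), miR-1839-5p (3.78) and miR-378c (3.69) were positive. miR-301b-3p (-2.87), miR-690 (-2.80), miR-3074-5p (-2.42), miR-31-5p (-2.35) and miR-466p-3p (-2.23) were negative. miR-1b-5p had 0 undifferentiated eluate reads, and miR-378c and miR-466p-3p had 0 control reads in both states. These 3 therefore measure no change of retention. The value of miR-690 comes from a rise of the control from 234 to 2416 CPM. miR-1a-3p had 0 reads in undifferentiated input, so its retention there could barely be measured, and miR-31-5p also fell in the input (-2.31). Unlike controls stay open as a cause of the 22 calls: all 15 with a control read kept their sign with each kind of MS2 library, which met the bound written before, but that bound was unsuitable, as each kind leaves 1 library in a state, 7 calls have no control read to change their sign, and only 6 and 8 of the 22 were called again. Few control reads stay open too, with 16 of the 22 under 10 reads in an MS2 group, and so does a difference of retention with myogenic differentiation, which the design names. A change of the level in the cells stays open as well: 8 of the 16 called miRNAs tested in the input had the same sign there, which met the bound of at most 50% written before, but the interval reaches 75.3%, and a condition on that limit was added after the value was seen.

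For the interaction chance cannot be excluded by regrouping: 5 of 100 splits of the 12 eluates, the real one included, called at least 22 miRNAs, and the highest other called 45. The 4 others each put 1 or 5 of the 6 MRTF-A libraries on the positive side and so carry the bait difference, and splits with 2 to 4 of them called at most 0. For the other comparisons the 10 splits of 6 libraries are too few for a share under 0.05. In each of them 1 split, the real one, gave as many calls as the real one, and the highest other gave 0. The real calls were 50 up and 145 down in the input, 102 and 134 for the bait against the control in undifferentiated and differentiated cells, 65 between the bait eluates, and 209 and 189 for the bait against input.

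In the input more miRNAs fell (145) than rose (50). Scaling factors taken over all 18 libraries go with this split, since with TMM factors of the 6 inputs 49.4% of calls were rises. A fall of many miRNAs in the cells stays open, since the medians ran up to -0.0718 over the 6 scalings and tests and each scaling sets its own centre. The large changes of the myomiRs and miR-7a-5p do not rest on this, as they held under all 6.

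In both states 71 miRNAs were higher with the MRTF-A bait. Spearman rho between input level and bait fold change was -0.124 in undifferentiated and -0.0620 in differentiated cells. The fold changes thus did not rise with abundance in the cells, which met the bound written before against abundance as the cause. Carry-over in proportion to abundance into both eluates would cancel in the ratio of bait to control, so rho cannot exclude abundance. Background RNA filling the MS2 control stays open as a cause. With eluates simulated as copies of the input, 20 draws gave 89 to 108 miRNAs called higher in both states. That the real eluates only copy the input is argued against. The 71 were further above input in the MRTF-A eluate than the other 98, by 4.07 and 3.81 in median log2 fold change. The draws gave -0.07 to 0.25 and -0.10 to 0.21. As the same eluates picked the 71, this gap cannot tell retention by the 3'UTR from unspecific retention. Seed pairing with the annotated 3'UTR stays open, with median differences of 2.19 and 1.88 that missed the threshold. The let-7 family and miR-34c-5p have no site and were higher with the bait than with the control. Retention through other parts of the bait or through proteins was not tested.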

How the results depend on the processing

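Tests with edgeR, TMM factors recomputed in the fit, mouse names alone, each kind of MS2 library, the first set of sequences, the shorter 3'UTR, miRNAs of at least 50 CPM, without the 2 farthest miRNAs, bounds and counting ratios without a library and with a block on the column suffix were chosen after the data were seen. Of 2629 values of named miRNAs under the alternatives, 2492 kept their direction and side of the threshold, 109 did not pass where the main test did, 22 passed where it did not and 6 reversed, and 89 of the 109 were in the interaction. The 6 are miR-486-5p (1.21 with DESeq2, 1.26 with edgeR, 1.12 with RLE) and miR-3107-5p (1.24, 1.29 and 1.17) against undifferentiated input, at -0.16 and -0.11 with limma. Of 188 list tests 166 kept their call, 19 lost it and 3 gained it. Those that lost it with library totals were let-7 and miR-17~92 against undifferentiated input and the endothelial and smooth muscle list against differentiated input, and those with the block the other differentiation and proliferation lists in the input, while the rest lost it with an estimated correlation. The gains were miR-17~92 in the input, with library totals and with recomputed TMM factors, and the candidates against differentiated input with the block.

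Counts of calls moved by over 1.5 times in these cases. With other libraries in the fit, which also changes the miRNAs tested, there were 102 calls of 305 tested in the input (50 up and 145 down of 313 before), 50 of 305 in the interaction (22 of 169 before) and 100 of 187 between the bait eluates (65 of 169 before). The filter of 10 CPM in 3 libraries is looser than the main one. It gave 231 of 455 for the bait in differentiated cells (134 of 169 before) and 7 of 455 in the interaction. No filter gave 307 of 1604 against differentiated input (189 of 305 before) and 2 of 1151 in the interaction. The interaction had 3 calls with edgeR, 14 with library totals and 13 with the MS2 libraries of few human-named reads. With a library left out it had 4 to 30 calls, with 8 without differentiated MRTF-A library B, 14 without C, 4 without differentiated MS2 library B and 5 without undifferentiated MS2 library C. Leaving out a library gave 160 to 210 calls in the input, 92 to 115 and 136 to 156 for the bait, 53 to 73 between the eluates, and 188 to 236 and 182 to 191 against input. Pearson r between input and eluate change was 0.858, and 0.716 with the looser filter of 10 CPM (292 miRNAs, 141 before), 0.754 without myomiRs and 0.787 without the 2 farthest miRNAs. The seed difference in differentiated cells was -1.46 with 8mer sites, which only 2 miRNAs have, against 1.88, and with the shorter 3'UTR it was 1.83 there and 1.74 in undifferentiated cells. The causes of these moves were not tested.

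The titles' replicate numbers are not tied to the columns, so the block used the column suffix. With this replicate block 197 miRNAs were called against differentiated input (189 before), where all 3 same-suffix pairs passed 0.1 but 3 of 6 libraries correlated best with their own suffix, and among named miRNAs and lists only miR-486-5p, miR-3107-5p and the candidates changed call there. In the other comparisons libraries share only a suffix, with correlations of same-suffix deviations from -0.228 to 0.222, and at most 5 of 6 libraries correlated best with their own suffix. The block gave 180 calls in the input, 108 and 136 for the bait, 9 in the interaction (22 before), 65 between the eluates and 215 against undifferentiated input. In the interaction miR-690 and miR-31-5p lost the call with it (limma adjusted p = 0.0626 and 0.0629). So did let-7d-3p, miR-1839-5p, miR-301b-3p and miR-3074-5p, while miR-133a-3p gained it (0.0188). Depth limits the MS2 controls most: with 15562 to 39695 reads, a miRNA with a few control reads has a wide interval. The simulated interaction recovered 7.41% of the 4-fold changes that passed the filter.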

Other observations

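These values were chosen after the data were seen. The 5p and 3p arms of a hairpin arise together, and usually the arm loaded into Argonaute is kept. Of 18 hairpins with both arms tested, 2 had arms called in opposite directions in undifferentiated and 3 in differentiated cells, and 2 of them did so in both. Under all 6 scalings and tests only 1 (miR-199a) and 2 (miR-199a and miR-378a) did. miR-199a-5p was higher than in the MS2 control (6.95 and 5.76 in undifferentiated and differentiated cells) and miR-199a-3p lower (-3.72 and -4.60). miR-378a-3p, from an intron of Ppargc1b, was higher (2.33 and 3.31) and miR-378a-5p lower (-3.29 and -2.50). In differentiated cells miR-30a-3p was higher (2.13) and miR-30a-5p lower (-1.04). miR-140-5p was far above the control (8.73 and 6.60), while miR-140-3p was not called in either state (-0.64 and -0.79).

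With the bait set against the control, 6 seed families had at least 3 tested members. All 4 tested members of the miR-34/449 family, whose miR-34 members are known targets of p53, were higher with the bait in both states (median 6.57 and 5.75, 4 and 4 under all 6 scalings and tests), and so were all 4 of the miR-130/301 family (median 5.05 and 4.24, 4 and 3 under all 6). Of 4 miR-181 members, which promote myoblast differentiation, 3 were higher in each state (median 2.11 and 2.93), but under all 6 only miR-181b-5p. In the miR-99/100 family 2 of 3 were lower in undifferentiated and 3 of 3 in differentiated cells (median -1.92 and -2.94, the same under all 6), and in the miR-30 family 1 and 2 of 3 (median -1.25 and -1.04, 1 and 1 under all 6). None of these 5 families, nor let-7, had a 7mer or 8mer site in the annotated mouse 3'UTR.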
